A study of Mus musculus with 4 samples.

How the data were processed

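RNA from mouse cells was measured on 4 single-colour Agilent expression arrays, 1 array per group. The groups were mouse embryonic fibroblasts (MEF), fibroblasts at day 2 after infection with the SeVdp(KOSM) vector, fibroblasts at day 2 after infection with the SeVdp(GKOSM) vector, and mouse induced pluripotent stem cells (miPSC). Per the labels' protocols, infection was carried out at 32 °C for a day and was followed by a day in mouse embryonic stem cell medium, and total RNA was labelled with Cy3. The labels do not spell out the letters of either vector name. The same protocol text is attached to all groups, MEF and miPSC included, and MEF is read here as uninfected because its own labels name no vector. Whether MEF was kept at 32 °C is not stated.

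The scanner files hold 45018 spots per array, of which 43379 were not controls and represented 41174 probes. Per the file headers, spot intensity was extracted with Agilent Feature Extraction 10.7.3.1, which subtracted background, removed spatial trends and set surrogate values for dim spots, with no scaling between arrays. The flags for background, saturation and outliers come from the same software, per the file headers. The deposited series table of intensity values equals the processed signal at all 45018 spots of each array, so its scale is linear and uncentred. Its column medians were 49.75 for MEF, 51.17 for GKOSM day 2, 53.36 for KOSM day 2 and 47.44 for miPSC. The authors' choice of scaling between arrays is not given in the sources used here.

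For each array, log2 of the processed signal was taken and the array's 75th percentile over non-control spots was subtracted. Spots with an outlier flag were left out, which removed 80 probes, and repeated spots of a probe were averaged. Where several probes carried 1 gene name, as for 8651 genes, the probe with the highest mean signal over the 4 arrays was used with its own background flag. This use of the probe's own flag replaced an earlier version, after first values were seen, in which any probe of the gene could count as above background. Of the 41174 probes, 24367 (59.2%) were named through their transcript accession with the GRCm38.p6 RefSeq gene table, used for names alone, and 4781 names differed from those in the files. Other probes kept the name in the file, giving 28440 genes or named transcripts. Probe positions are those of the file annotation, build mm8.

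A gene was counted as higher or lower when the log2 difference was 1.0 or more in size, that is 2-fold. Where a probe was well above background on 1 of the 2 arrays, the dim side was set to the higher of its own signal and the lowest signal well above background on that array, and the fold is written as "at least". Genes not well above background on either array were not compared. A gene dim on 1 array thus enters only through the array where it is above background, and its difference cannot take the other sign. No spot was saturated. The floor on the scaled log2 axis was -6.85 for MEF, -6.91 for GKOSM day 2, -6.26 for KOSM day 2 and -6.72 for miPSC.

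With 1 array per group there is no replicate check of any difference, no test was made and no p-value is given. The number of arrays limits the precision. Of 245 probes printed 10 times each, those well above background gave the spread between spots, with a median log2 SD of 0.0761 for MEF (182 probes) and, over 178 probes each, 0.0817 for KOSM day 2, 0.0856 for GKOSM day 2 and 0.0704 for miPSC. This spread covers spot noise and leaves out labelling, hybridisation and differences between cultures. MEF, GKOSM day 2 and KOSM day 2 shared a slide and miPSC was on another, so slide and group cannot be told apart in any comparison with miPSC.

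Before the data were examined, 32 gene lists, the rule for named genes and most alternatives were set. Of 639 list members, 627 were found on the array. The median of a list was set beside 10000 random lists of the same size, matched on mean signal in 20 bins, and a list is said to stand apart at or below percentile 2.5 or at or above 97.5. This percentile describes these arrays and is not a test. Named genes were, per comparison, the 8 highest and 8 lowest differences measured on both arrays, the 3 largest bounds in each direction, up to 3 members of each list that stood apart or had a median of at least 0.5 in size, up to 2 members of those lists that went the other way, and in every comparison Klf4, Pou5f1, Sox2, Myc, Glis1, Nanog, Esrrb, Lin28a, Tcl1, Cdh1, Epcam, Thy1, Snai2, Zeb1, Col1a1, Cdkn2a, Ifit1 and Isg15. Clone names and predicted genes were left out of the highest and lowest differences. The rule took 291 genes in all, and the text gives a part of them, picked after their values were seen; a few genes that the rule took are not reported here.

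Comparisons that share the MEF array were set beside 20 simulations of unchanged arrays made from MEF signal and spot noise, which hold no differences between cultures, and beside the overlap of independent lists. The steps were tested on simulated data for the comparison of KOSM day 2 with MEF, with 18404 genes compared. Of 50 genes altered by 1.25 on the log2 scale, 98% were recovered, and for 1.50, 2.00 and 3.00 the shares were 100%, 100% and 98%. In the same simulation 108 of 18204 unaltered genes passed the threshold. These shares do not cover differences between cultures, which 1 array per group cannot give.

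Alternatives were quantile normalization, scaling to the median of probes above background on all arrays, normexp background correction with an offset of 50 in limma 3.58.1 under R 4.3.3, the series table without scaling, the mean of all probes of a gene, stricter or no filtering of dim probes, a 4-fold threshold, a 2-fold set for the position between MEF and miPSC, and unmatched random lists. Scaling by the median of 8 spike-in probes and a filter on genes above background on all 4 arrays were added after the data were seen. The median over spike-in probes replaced their mean after their values were seen, since 1 probe differed from the others on the KOSM day 2 array. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.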

Results

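Gene expression was measured in mouse cells during reprogramming with SeVdp, a vector made from Sendai virus. One RNA sample was hybridised per group, giving 4 arrays: mouse embryonic fibroblasts for which no vector is named (MEF), cells at day 2 after infection with the KOSM vector, cells at day 2 after infection with the GKOSM vector, and mouse induced pluripotent stem cells (miPSC). Of the non-control spots, 66.5% were well above background on the MEF array, 62.7% on the KOSM array, 66.2% on the GKOSM array and 66.5% on the miPSC array. The 75th percentile of signal, to which each array was scaled, was 800 in MEF, 919 with KOSM, 895 with GKOSM and 757 in miPSC. There are no replicates, so every difference is a difference between single arrays and has no replicate check. Levels are given as log2 signal minus the array's 75th percentile, and positions are those of the probes on mouse build mm8.

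Transcripts of known reprogramming factors were read first. Signal of the single Klf4 probe (chromosome 4, 55549061 to 55549120) was 5.60 in MEF, 3.14 with KOSM, 2.92 with GKOSM and 5.41 in miPSC. Pou5f1 (chromosome 17, 35118388 to 35118448) was well above background in miPSC alone, at 4.12. Sox2 (chromosome 3, 34843400 to 34843459) was well above background with KOSM at -4.16 and in miPSC at 3.56. Myc had levels of 0.71 in MEF, 0.65 with KOSM, -0.33 with GKOSM and -0.14 in miPSC, and Glis1 had 0.67, 1.01, 0.29 and -3.39 in the same order. Whether these probes lie within the sequence carried by the vectors is not known here, so they do not check the labels.

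**Figure D1:**
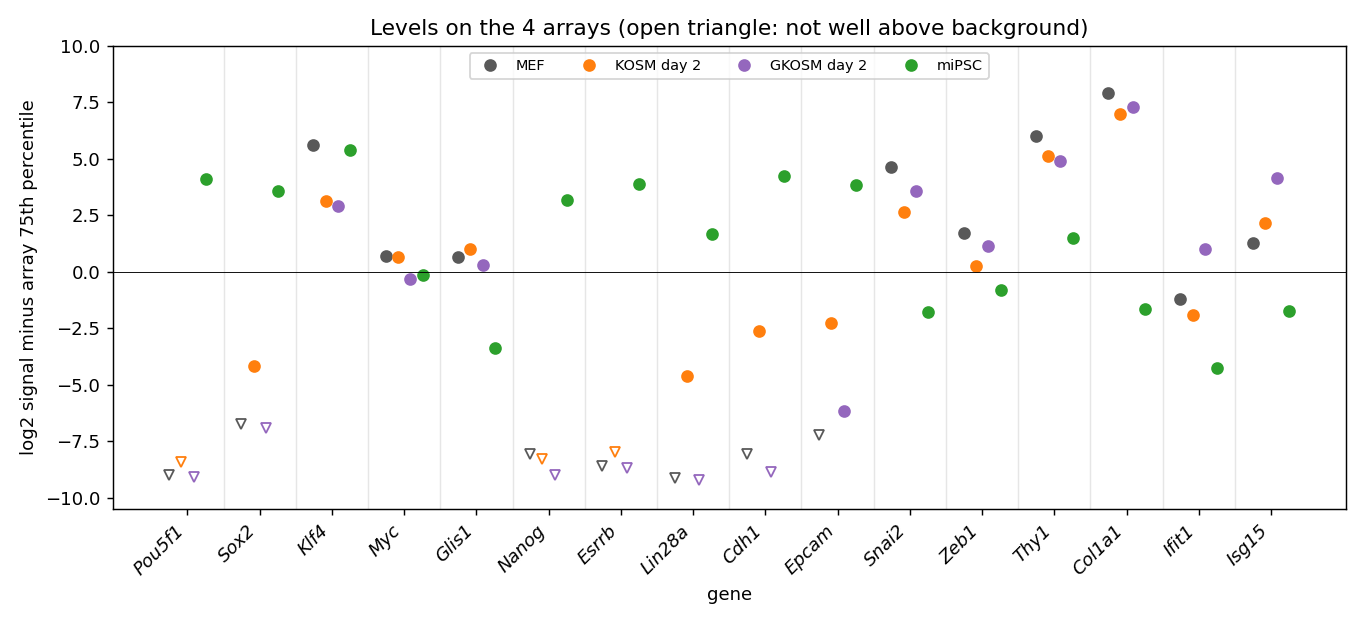
Signal of selected genes on each of the 4 arrays, as log2 signal minus the array's 75th percentile, with 1 point per array and open triangles where the probe was not well above background. Pou5f1 reaches 4.12 in miPSC and is not well above background on the other arrays, and Ifit1 stands at 1.01 with GKOSM against -1.89 with KOSM.

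The comparison of KOSM day 2 cells with MEF asked how the transcriptome differed 2 days after infection with this vector. Cell cycle and ribosome biogenesis genes were higher by day 2, epithelial genes were higher, and genes of the fibroblast matrix and mesenchymal transcription factors were lower. Tdh, which encodes threonine dehydrogenase, had the largest difference measured on both arrays, 937-fold higher (log2 9.87, spot SD 0.26). Pou5f1, Nanog and Esrrb were not well above background on either array. Among 19265 genes compared, 4264 were at least 2-fold higher and 4200 at least 2-fold lower, of which 719 and 693 are bounds. In simulated unchanged arrays, which carry spot noise and no difference between cultures, at most 68 genes were higher and 65 lower.

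Next to Tdh (chromosome 14, 62446600 to 62446659), the highest measured differences with KOSM were those of the imprinted gene Phlda2 (log2 9.07; chromosome 7, 143310959 to 143311018), the acyl-CoA synthetase gene Acsl6 (8.87), Hpdl (8.81), Bspry (8.64), the zinc finger gene Zfp296 (7.90), the keratin gene Krt84 (7.87) and the Wnt receptor gene Fzd10 (7.51). Of these, Fzd10 (-6.56), Krt84 (-6.29) and Acsl6 (-6.20) lay near the floor of -6.85 in MEF, so their folds are less precise. Signals not well above background in MEF gave bounds of at least 638-fold for Nkx6-2, at least 637-fold for Slc10a4 and at least 319-fold for the Notch ligand gene Jag2. The lowest differences were those of Pamr1 (-6.26), Sncaip (-6.26), Igfbp5 (-6.23; chromosome 1, 72791462 to 72791521), Angptl1 (-6.12), the alcohol dehydrogenase gene Adh1 (-6.02), the collagen gene Col8a2 (-5.96), Chrdl1 (-5.76) and Lgr5 (-5.64).

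Of 18 measured genes of epithelial junctions and keratins, 14 were higher with KOSM than in MEF, 1 was lower and 3 differed less than 2-fold, with a list median of 2.39. Of these values 4 are bounds, and 7 more members were dim on both arrays. The adhesion genes Epcam and Cdh1 were at least 23.8-fold and at least 19-fold higher, the desmosome gene Dsp was 21.7-fold higher, and Krt19 had -1.01. Of 17 mesenchymal transcription factors 13 were lower, 1 was higher and 3 were under 2-fold, at a median of -1.69. Meox2 had -4.09, Snai2 -1.99 and Zeb1 -1.43, whereas Foxc2 had 1.33. In the fibroblast matrix list 28 of 37 genes were lower, 2 were higher and 7 were under 2-fold, with a median of -1.81. Elastin (Eln) was lower by 41.1-fold and lumican (Lum) by 15.4-fold, while Cd44 was 4.17-fold higher and Timp1 2.49-fold higher. Thy1 had -0.86 and Col1a1 -0.91, with -2.25 and -2.38 from the other Col1a1 probes. The smooth muscle list had 8 of 14 genes lower and 6 under 2-fold (median -1.09), and the TGF-beta list had 9 lower, 2 higher and 11 under 2-fold (median -0.77), led by Bmp4 at -4.03.

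DNA replication genes were higher for 27 of 28 members with KOSM, at a median of 2.07, and 1 was under 2-fold. Cyclin E2 (Ccne2) had 4.36 and the licensing factor Cdc6 had 4.08. Of 25 mitosis genes 24 were higher and 1 was under 2-fold (median 2.43), with Aurka at 3.34 and Ccnb1 at 3.24, and the cell cycle inhibitor gene Cdkn2a had -1.27. Among 21 Myc family and ribosome biogenesis genes 20 were higher and 1 was lower (median 2.5). Rrp9 had 4.24 and Nolc1 3.90, while Mycn was at least 4.70-fold lower and Myc itself had -0.06, with -0.16 and 0.23 from its other probes. Glycolysis genes were higher for 10 of 20, lower for 1 and under 2-fold for 9 (median 0.95), and included the lactate transporter gene Slc16a1 (3.73) and hexokinase 2, Hk2 (3.70). DNA methylation and chromatin genes were higher for 10 of 23, lower for 1 and under 2-fold for 12 (median 0.95), led by the de novo methyltransferase gene Dnmt3b (4.47).

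Pluripotency genes were mixed with KOSM. Of 20 measured members 8 were higher, 2 lower and 10 under 2-fold, and the median of 0.55 lay at percentile 97.0 of random lists, short of standing apart. Bounds make up 3 of these values, and 7 more members were dim on both arrays. Zfp296, Mybl2 (4.13) and the alkaline phosphatase gene Alpl (3.24) were among the higher members, Lin28a was at least 4.65-fold higher and Tcl1 had 0.58. Dppa5a had -1.07 from 1 probe and 0.05 from another. Imprinted genes were lower for 15 of 19 and higher for 2 (median -1.97), with Cdkn1c at -4.24 and Peg3 at -3.86, against Phlda2 at 9.07 and Peg10 at least 29.0-fold higher. Interferon-stimulated genes were lower for 14 of 42, higher for 5 and under 2-fold for 23 (median -0.76). Gbp2 had -3.24, Irf1 -2.24, Stat2 -2.22 and Ifit1 -0.70, while Cxcl10 had 2.71 and Isg15 0.88.

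Wnt signalling genes were lower for 15 of 28, higher for 7 and under 2-fold for 6 (median -1.38), with Sfrp2 at -3.56 and Nkd2 at 4.40, and Lef1 at least 61.6-fold higher. Cholesterol synthesis genes were lower for 10 of 17 and under 2-fold for 7 (median -1.36), including Mvd at -1.93. Of 9 measured 2-cell-stage and germline genes 7 were higher, 1 was lower and 1 was under 2-fold (median 1.37), with Tcstv3 at 3.22 and Ddx4 at -2.67. Of these values 5 are bounds, and another 9 members were dim on both arrays and not compared. Trophectoderm genes were higher for 7 of 14, lower for 4 and under 2-fold for 3, with a median of 1.20 that became -0.49 when only genes well above background on both arrays entered. Tead4 had 4.40 and Tfap2c was at least 20.3-fold higher. Scaling by spike-ins moved the median of all genes by 0.441 in this comparison, and the share of higher genes among those 2-fold apart was then 71.6% against 50.4% with the 75th percentile. With spike-in scaling the list medians were -0.25 for interferon, -0.26 for TGF-beta, -0.58 for smooth muscle, -0.85 for cholesterol, -0.88 for Wnt, 1.06 for pluripotency and 1.46 for both glycolysis and chromatin genes.

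The comparison of GKOSM day 2 cells with MEF asked the same of the second vector. Cell cycle, ribosome biogenesis and interferon-stimulated genes were higher with GKOSM, and most genes of the matrix, mesenchymal, imprinted and Wnt lists were lower. The 8 highest measured differences were those of the Wnt receptor gene Fzd10, 121-fold higher (log2 6.92, spot SD 0.50; chromosome 5, 128918631 to 128918690), Hpdl (6.50), Phlda2 (6.08), Lingo3 (5.76), the mast cell chymase gene Cma1 (5.53), the histone gene H3c1 (5.40), Dcaf12l1 (5.18) and Zfp296 (5.17). In MEF, Fzd10 (-6.56) and H3c1 (-6.64) lay near that array's floor of -6.85, so their folds are less precise. Of 19350 genes compared, 3179 were at least 2-fold higher and 3567 at least 2-fold lower, of which 426 and 536 are bounds. Among genes 2-fold apart 47.1% were higher, and 57.1% in the series table without scaling.

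Anxa10 was at least 877-fold higher with GKOSM, the nuclear pore gene Nup210 at least 316-fold and Jag2 at least 175-fold. Among the lowest measured differences were those of the scavenger receptor gene Scara5 (-6.78; chromosome 14, 64718177 to 64718236), Col26a1 (-5.46), Chrdl1 (-5.25), Pamr1 (-5.08), Lbp (-5.07), Megf6 (-5.01) and Egfl6 (-5.00). Pou5f1, Sox2, Nanog, Esrrb, Lin28a and Cdh1 were not well above background on either array. Klf4 had -2.68, Myc -1.04, Glis1 -0.38 and Tcl1 -0.03.

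Interferon-stimulated genes were higher for 28 of 45 measured members with GKOSM, lower for 1 and under 2-fold for 16, with a median of 1.41. The chemokine gene Cxcl10 had 5.09 (chromosome 5, 93421955 to 93422014), the oligoadenylate synthetase gene Oas1a 4.33 and Rsad2 3.91. Isg15 had 2.88 and Ifit1 2.20 (chromosome 19, 34715303 to 34715362), and Irf1 was the member that was lower, at -1.17. DNA replication genes were higher for 27 of 28 and under 2-fold for 1 (median 2.44), with Ccne2 at 3.86 and Rrm2 at 3.43. All 25 mitosis genes were higher (median 2.56), with Bub1b at 3.32, and Cdkn2a had -0.43. Myc family and ribosome biogenesis genes were higher for 20 of 21 (median 2.05), with Dkc1 at 3.29, and Mycn was at least 7.88-fold lower. Glycolysis genes were higher for 9 of 20 and under 2-fold for 11 (median 0.80), with Hk2 at 2.33, and chromatin genes were higher for 11 of 23, lower for 1 and under 2-fold for 11 (median 0.98), with Dnmt3b at 2.59.

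Fibroblast matrix genes were lower for 30 of 37, higher for 1 and under 2-fold for 6 with GKOSM (median -1.75). Lum had -4.18, Eln -3.79, decorin (Dcn) -3.64, Thy1 -1.09 and Col1a1 -0.60, with -1.73 and -1.79 from the other Col1a1 probes, and Cd44 had 1.18. Mesenchymal transcription factors were lower for 10 of 17 and under 2-fold for 7 (median -1.08), among them Meox1 (-3.99) and Snai2 (-1.08), and Zeb1 had -0.56. The TGF-beta list had 13 of 22 genes lower and 9 under 2-fold (median -1.09), with Bmp4 at -3.03, and the smooth muscle list had 4 of 14 lower and 10 under 2-fold (median -0.75). Epithelial genes were higher for 5 of 16, lower for 3 and under 2-fold for 8 (median 0.67, and -0.01 with no filter on dim probes). The protease gene St14 had 3.54, Cd24a 2.83 and Cldn7 -2.03, and Epcam was at least 1.60-fold higher. Pluripotency genes had a median of -0.21 over 19 members, of which 5 were higher, 1 lower and 13 under 2-fold, and this list did not stand apart.

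Imprinted genes were lower for 16 of 19 with GKOSM and higher for 3 (median -1.88), with Cdkn1c at -3.99. Wnt signalling genes were lower for 16 of 26, higher for 3 and under 2-fold for 7 (median -1.77), including Lgr5 at -4.45, while Lef1 was at least 16.1-fold higher. LIF and STAT3 genes were lower for 9 of 16, higher for 2 and under 2-fold for 5 (median -1.17), with the receptor subunit gene Il6st at -2.41, Socs3 at -2.38 and Fosl1 at 2.75. Cholesterol synthesis genes were lower for 9 of 17 and under 2-fold for 8 (median -1.06). The unfolded protein and heat shock list had 5 of 17 genes lower, 2 higher and 10 under 2-fold (median -0.56), with Trib3 at -2.38 and Ddit3 at -2.30 against Hsph1 at 2.06. Trophectoderm genes were lower for 5 of 9 and under 2-fold for 4 (median -1.09), and neural genes lower for 4 of 12, higher for 2 and under 2-fold for 6 (median -0.81). Scaling by spike-ins moved the median of all genes by 0.121, and the series table without scaling moved it by 0.171, in this comparison and by 0.141 in that of KOSM with MEF.

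**Figure D2:**
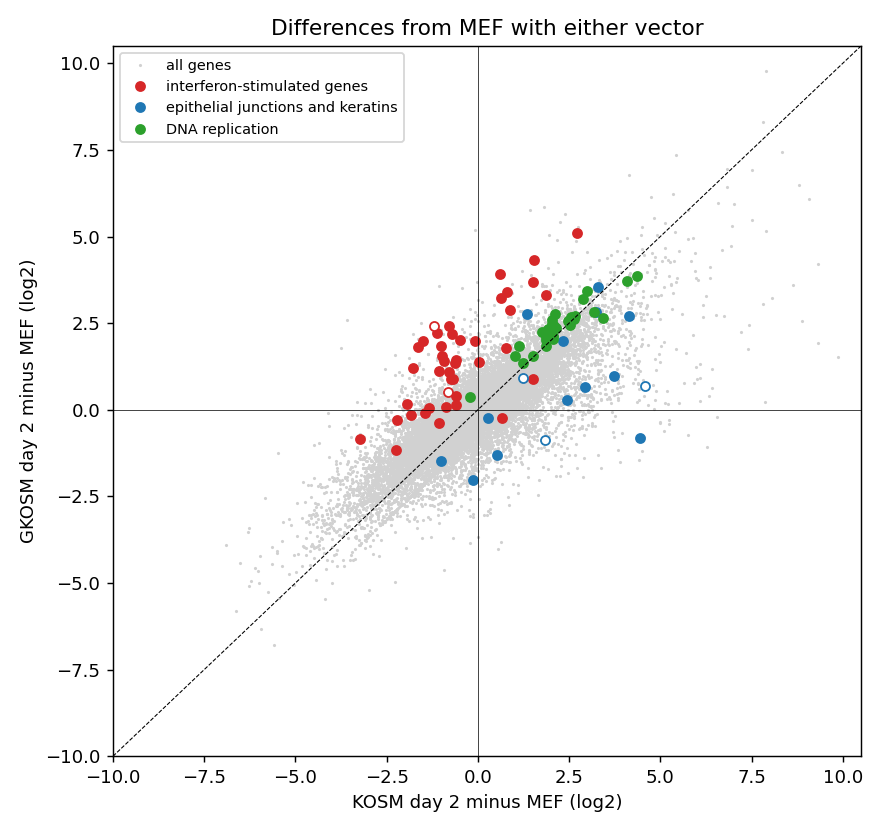
Log2 difference from MEF with the KOSM vector (x axis) and with the GKOSM vector (y axis), 1 point per gene, with interferon-stimulated genes in red, epithelial genes in blue, DNA replication genes in green, open symbols where a gene was not well above background on at least 1 of the 3 arrays, and a dashed line of equal difference. Interferon-stimulated genes mostly lie above the line, with medians of -0.76 with KOSM and 1.41 with GKOSM, and DNA replication genes lie near it at 2.07 and 2.44.

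The differences of both vectors from MEF were alike over most genes. Across 15709 genes well above background on all arrays, Pearson's r between them was 0.823 and Spearman's rho 0.814, where genes are not independent replicates. Both differences share the MEF array, and simulated unchanged arrays, which hold spot noise alone, gave a mean r of 0.5 (range 0.484 to 0.519). The covariance was 1.337 against 0.022 in the simulation, a difference of 1.315. Among 18848 genes compared with both vectors, 2361 were higher with both, where independent lists of 3905 and 2993 genes would share 620.1 and simulated unchanged arrays 6.1. For lower genes 2664 were shared from lists of 4200 and 3567, against 794.9 and 13.8. Opposite differences of at least 2-fold were found for 55 genes higher with KOSM and lower with GKOSM and for 31 genes with the reverse pattern. Part of the excess may come from the shared MEF array. Per the labels' protocols, both vector cultures also shared the infection temperature and the later mouse embryonic stem cell medium. Whether MEF had the same temperature or medium is not known here. In these differences from MEF, infection, temperature and medium therefore cannot be told apart from the sequence carried by the vectors.

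The direct comparison of GKOSM with KOSM at day 2 asked what differs between the vectors at the same time point. Interferon-stimulated genes were higher with GKOSM for 39 of 45 measured members, and the other 6 differed less than 2-fold (median 2.00). Epithelial genes were lower with GKOSM for 11 of 18, higher for 1 and under 2-fold for 6 (median -1.87), and pluripotency genes were lower for 8 of 19 and under 2-fold for 11 (median -0.61). Of 18918 genes compared, 1593 were at least 2-fold higher and 2066 at least 2-fold lower with GKOSM, of which 302 and 518 are bounds. Spike-in scaling moved the median of all genes by -0.346, and the share of higher genes among those 2-fold apart was then 16.8% against 43.5% with the 75th percentile.

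Among interferon-stimulated genes, the GTPase gene Iigp1 was 11.2-fold higher with GKOSM than with KOSM (log2 3.49, spot SD 0.11; chromosome 18, 60517868 to 60517927), Trim30a 10.9-fold, Ifit1 7.47-fold and Isg15 3.99-fold, and Oas2 was at least 12.2-fold higher. The macrophage and blood list had a median of 0.29, which turned to -0.09 under spike-in scaling, with the macrophage gene Lyz2 at 0.76. The highest measured differences were those of Dcaf12l1 (37.9-fold, log2 5.24; chromosome X, 41031210 to 41031269), the protocadherin gene Pcdh10 (4.63), Spag16 (4.34), Rims2 (4.01), Foxp2 (3.99), the interferon-inducible GTPase gene Tgtp1 (3.95), Pcdh17 (3.95) and the GABA receptor gene Gabrb2 (3.73). Dach2 was at least 71.7-fold and Sucnr1 at least 44.0-fold higher.

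Tdh had the lowest difference of GKOSM from KOSM, 328-fold lower (log2 -8.36, spot SD 0.16), followed by Krt84 (-7.66), Slc10a4 (-7.37), Smagp (-6.74), the osteocalcin gene Bglap (-6.51), Acsl6 (-6.31), Krtap13 (-5.87) and the lymphotoxin gene Ltb (-5.86). Mcoln2 was at least 162-fold lower and the epithelial transcription factor gene Ovol1 at least 118-fold. Dsp was 38.4-fold lower with GKOSM (chromosome 13, 38205718 to 38205777), Epcam 14.9-fold, and Cdh1 at least 19.8-fold (chromosome 8, 109559041 to 109559100). Zfp296 had -2.73, Utf1 -2.69 and Tcl1 -0.61, and Lin28a was at least 4.85-fold lower. Pou5f1, Nanog and Esrrb were not well above background on either array.

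Trophectoderm genes were lower with GKOSM than with KOSM for 7 of 14 and under 2-fold for 7 (median -1.26), with Tead4 at -3.62. Genes of the 2-cell stage and germline were lower for 6 of 11 and under 2-fold for 5 (median -1.06), and keratinocyte genes lower for 5 of 9 and under 2-fold for 4 (median -1.0). Bounds make up 5 of the trophectoderm values, 5 of the germline values and 1 of the keratinocyte values. In the same order 2, 7 and 3 more members were dim on both arrays. The LIF and STAT3 list had 6 of 16 genes lower and 10 under 2-fold (median -0.52), including Fosl1 at -1.77 and Egr1 at -1.46. The NF-kB and inflammatory list had 5 of 16 lower and 11 under 2-fold (median -0.45), the Myc and ribosome list 2 of 20 lower and 18 under 2-fold (median -0.44), and the Wnt list 9 of 28 lower, 1 higher and 18 under 2-fold (median -0.33), with Nkd2 at -3.36. Under spike-in scaling the medians were -0.84 for NF-kB, -0.83 for Myc and ribosome, -0.71 for Wnt, -0.90 for LIF and STAT3 and -1.0 for pluripotency genes. Of the reprogramming factors, Sox2 was at least 6.72-fold lower, Myc had -0.98, Glis1 -0.72 and Klf4 -0.22, and the list median was -0.85.

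Fibroblast matrix genes (median 0.17), smooth muscle genes (0.29), DNA replication genes (0.14) and oxidative phosphorylation genes (0.13) stood apart slightly on the higher side with GKOSM. Under spike-in scaling, which moves genes measured on both arrays alike, their medians were -0.22, -0.10, -0.25 and -0.26, and all 4 still stood apart on the higher side of random lists (percentiles 98.9, 99.3, 97.6 and 99.5). Mitosis genes had a median of 0.12 that turned to -0.26, and chromatin genes had -0.03. Snai2 had 0.91, Zeb1 0.87, Cdkn2a 0.83, Col1a1 0.31 and Thy1 -0.23. Mesenchymal transcription factors had a median of 0.30, with 3 of 17 higher, 1 lower and 13 under 2-fold, and did not stand apart. Under spike-in scaling their median was 0.00, at percentile 97.7. Of the 17 values 1 is a bound, which cannot change sign when the scale moves, so this percentile is not read as a change.

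The comparison of miPSC with MEF set the end points of reprogramming side by side. Pluripotency, epithelial and germline genes were higher in miPSC by medians above 6 on the log2 scale, and matrix and mesenchymal genes were lower by as much. Pou5f1 was at least 2010-fold higher, Sox2 at least 1242-fold, Nanog at least 1059-fold (chromosome 6, 122679692 to 122679751) and Cdh1 at least 2208-fold. Periostin (Postn), a matrix protein gene, was lower by 6887-fold (log2 -12.75, spot SD 0.38; chromosome 3, 54478490 to 54478549). Of 20285 genes compared, 5734 were at least 2-fold higher and 4797 at least 2-fold lower, of which 1366 and 1176 are bounds. Slide and group cannot be told apart in this comparison.

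Of 27 measured pluripotency genes 23 were higher in miPSC and 4 were under 2-fold (median 7.37). Zfp42 was at least 5171-fold higher, Esrrb at least 1725-fold, Dppa3 at least 1400-fold and Lin28a at least 365-fold, with Fbxo15 at 9.34, Dnmt3l at 9.25 and Tcl1 at 7.26. Klf4 had -0.19, Myc -0.85 and Glis1 -4.06. Tdh was the highest measured gene (3277-fold, log2 11.68), followed by the homeobox gene Rhox5 (10.43), the aquaporin gene Aqp8 (9.66), Pipox (9.65) and Hkdc1 (9.54), and the laminin gene Lama1 had 9.20. Tex19.1 and Trap1a had bounds of at least 5952-fold and at least 3860-fold. Epithelial genes were higher for 23 of 25 and under 2-fold for 2 (median 6.28), with Epcam at least 1634-fold higher. All 18 measured 2-cell-stage and germline genes were higher (median 6.55), with Mael at least 1830-fold.

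All 37 fibroblast matrix genes were lower in miPSC (median -7.05), including Col3a1 at -11.02, Lum at -10.90, Col1a1 at -9.54 and Thy1 at -4.51. All 17 mesenchymal transcription factors were lower (median -6.28), with Prrx1 at least 2067-fold lower, Snai2 at -6.43 and Zeb1 at -2.50. Outside these lists Ptn had -12.16, the matrix Gla protein gene Mgp -12.07, Ogn -11.94, Itga11 -10.58 and the protease gene Adamts5 -10.52. Bounds were largest for Lrrc17, at least 7164-fold lower, Col5a2, at least 4031-fold, and the lysyl oxidase gene Lox, at least 2779-fold. Smooth muscle genes were lower for 11 of 14, higher for 1 and under 2-fold for 2 (median -3.32), with Acta2 at -6.98. TGF-beta genes were lower for 16 of 22, higher for 3 and under 2-fold for 3 (median -2.55), with Inhba at -9.48, and NF-kB and inflammatory genes were lower for 11 of 17, higher for 2 and under 2-fold for 4 (median -3.29), with Il1rl1 at -7.52 and Icam1 at 1.84.

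DNA replication genes were higher in miPSC for 27 of 28 (median 2.97), mitosis genes for all 25 (median 3.31) and Myc and ribosome genes for 20 of 21 (median 2.18), with Mycn at 7.54 and Cdkn2a at -3.0. Glycolysis genes were higher for 13 of 20 and under 2-fold for 7 (median 1.33), with the glucose transporter gene Slc2a3 at 7.16, and chromatin genes were higher for 18 of 23 and under 2-fold for 5 (median 1.87), with Dnmt3b at 6.32. Imprinted genes were lower for 14 of 19, higher for 3 and under 2-fold for 2 (median -2.56). Igf2 had -10.25, H19 -7.30 and Dlk1 -7.19, against 7.52 for Phlda2 and 3.13 for Snrpn. Interferon-stimulated genes were lower for 17 of 44, higher for 12 and under 2-fold for 15 (median -0.73), with Ifit3 at -6.44, Ifit1 at -3.05 and Isg15 at -3.0 against Oas1a at 5.18 and Cxcl10 at 3.69.

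Mesendoderm genes were higher in miPSC for 11 of 15, lower for 1 and under 2-fold for 3 (median 1.54), with Foxa2 at 7.94, Sox17 at 7.60 and Gsc at -2.61. Trophectoderm genes were higher for 8 of 14, lower for 3 and under 2-fold for 3 (median 1.74), and endothelial genes higher for 5 of 10, lower for 3 and under 2-fold for 2 (median 2.25). With only genes well above background on all 4 arrays these medians were -0.42, -0.26 and -0.25. That filter also leaves out Foxa2 and Sox17, which were well above background in MEF and miPSC but dim with KOSM. With genes above background on both arrays compared, the mesendoderm median did not change sign, while trophectoderm and endothelial genes again had -0.26 and -0.25. Wnt genes were lower for 15 of 30, higher for 10 and under 2-fold for 5 (median -0.74), with Dkk2 at least 589-fold lower and Tcf7 at 5.70. LIF and STAT3 genes were lower for 10 of 16, higher for 4 and under 2-fold for 2 (median -1.55), with Osmr at -6.68 and Lifr at 3.47. Cholesterol synthesis genes were lower for 6 of 17 and under 2-fold for 11 (median -0.66), and macrophage and blood genes lower for 8 of 13, higher for 3 and under 2-fold for 2 (median -1.80).

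**Figure D3:**
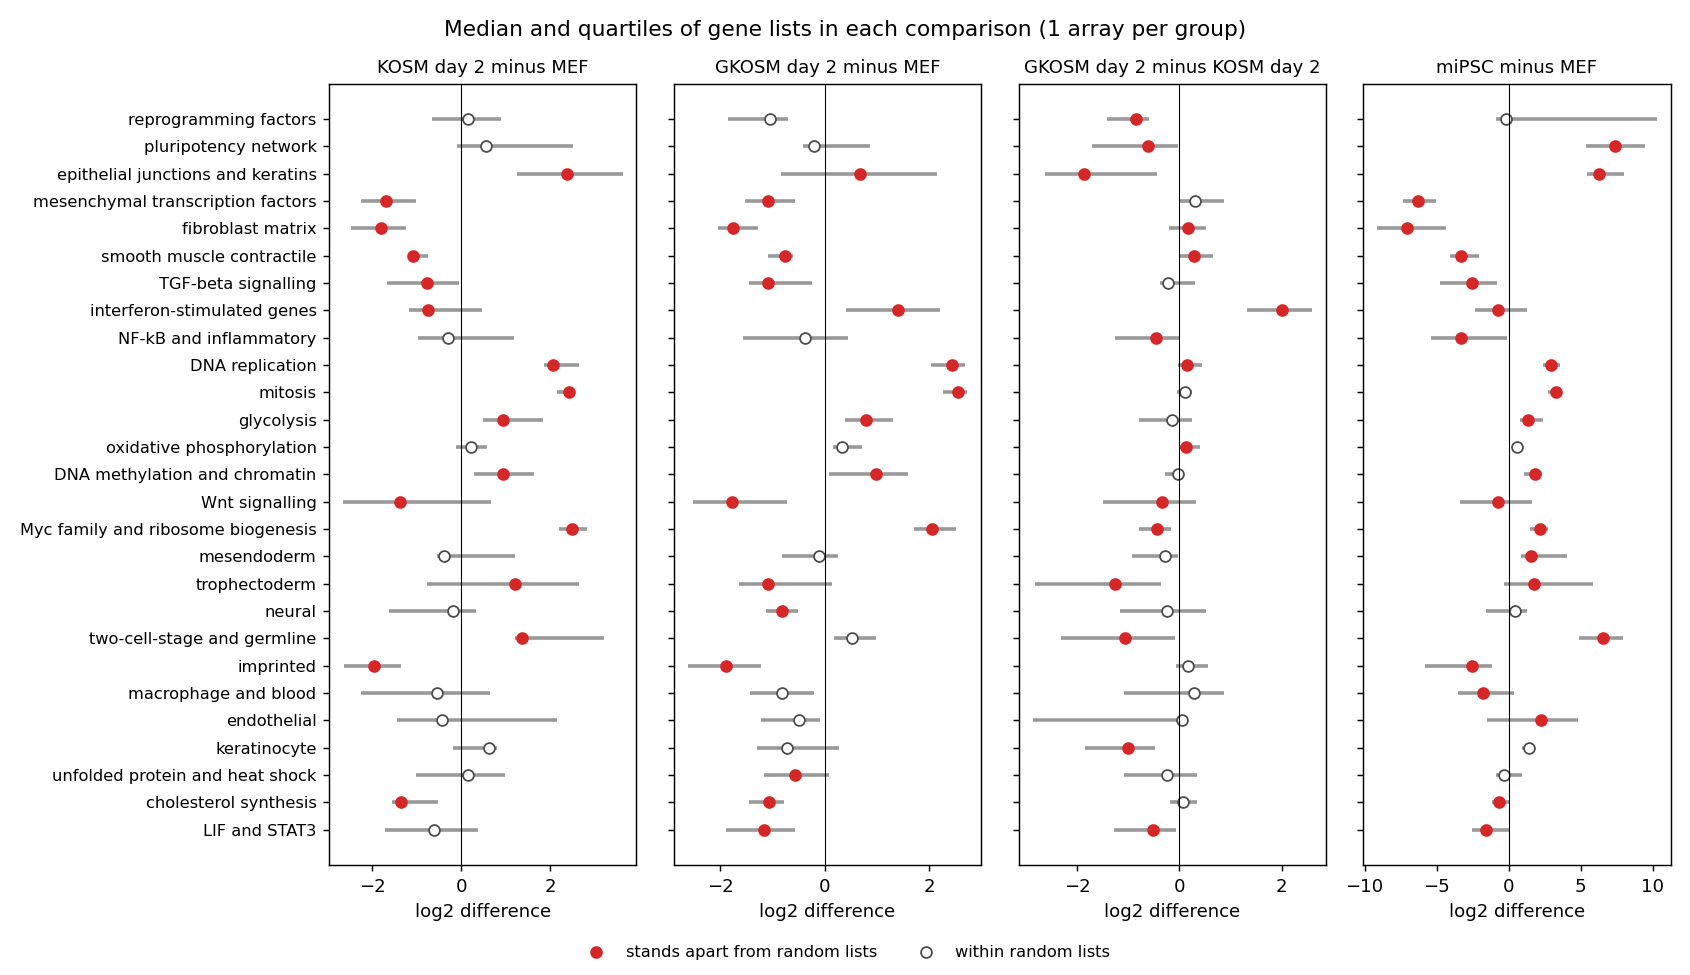
Median log2 difference of each gene list (points) with its quartiles (bars) in the 4 comparisons, with 1 panel per comparison and a wider x axis for miPSC minus MEF. Filled red points stand apart from random lists of matched signal and open points do not, and the 27 lists that stood apart in at least 1 comparison are drawn. The interferon-stimulated list stands at -0.76 with KOSM and at 1.41 with GKOSM, while 4 small medians of GKOSM minus KOSM (matrix 0.17, smooth muscle 0.29, DNA replication 0.14, oxidative phosphorylation 0.13), and that of mitosis at 0.12, fall below 0 under spike-in scaling with the shift of all genes, and the 4 lists still stand apart there.

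Day 2 cells were then placed between MEF and miPSC. Of 2816 genes at least 4-fold higher in miPSC than in MEF, 49.4% were at least 2-fold higher than in MEF with KOSM (exact 95% interval 47.5 to 51.3) and 40.6% with GKOSM (38.8 to 42.5), and 4.58% and 6.07% were at least 2-fold lower. Genes dim on both arrays count as not moved in these shares, and the higher genes were 1391 of 2199 compared with KOSM and 1144 of 2151 with GKOSM. Of 2486 genes at least 4-fold lower in miPSC, 69.4% were lower with KOSM (67.6 to 71.2) and 63.2% with GKOSM (61.3 to 65.1), an order that turned under spike-in scaling, to 54.6% and 58.5%. In this second set 2.98% were higher with KOSM and 2.29% with GKOSM. The intervals cover the counting of genes, which are not independent. Simulated unchanged arrays, which carry spot noise and no difference between cultures, gave at most 0.709% for the first set and 0.121% for the second. Both sets and the day 2 differences share the MEF array. Anything particular to that single MEF culture would count as movement toward miPSC with either vector, which the simulation does not cover. Over genes of the first set the median of GKOSM minus KOSM was -0.28, with 176 higher and 595 lower, and over the second set it was 0.29, with 417 higher and 180 lower. Under spike-in scaling, where the sets held 2925 and 2388 genes, these were -0.65, with 94 higher and 836 lower, and -0.05, with 228 higher and 314 lower. Across 15709 genes, GKOSM minus KOSM had a Pearson's r of -0.197 and a Spearman's rho of -0.182 with miPSC minus MEF, a pair that shares no array, against -0.023 to 0.041 in simulated unchanged arrays.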

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

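The tests of spike-in scaling, dim signal, macrophage RNA, mixture and slide offset were chosen after the results were seen, while quantile and median scaling were among the alternatives set before the data were examined.

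Interferon-stimulated genes had list medians of opposite sign relative to MEF, -0.76 with KOSM (14 of 42 members lower, 5 higher, 23 under 2-fold; -0.25 under spike-in scaling) and 1.41 with GKOSM (1.53 under spike-in scaling), and the difference between the groups was not tested because each has 1 array. Scaling as the whole cause is argued against by the median of GKOSM minus KOSM, 2.00, which stayed at 1.61 or more under the 75th percentile, quantile, median and spike-in scalings, and dim signal by a median of 2.02 over members well above background on all 4 arrays. More macrophage RNA with GKOSM, at unchanged expression per macrophage, is argued against by 10 measured macrophage markers. Their GKOSM minus KOSM had a median of 0.23 and a 75th percentile of 0.82, below the interferon median of 2.00. Adgre1 had 1.85 (-5.36 with KOSM, -3.51 with GKOSM). Lyz2, Fcer1g and Tyrobp were also higher with GKOSM than with KOSM, and Cd14 was lower. For GKOSM minus MEF the marker median was -1.38, where the interferon list had 1.41. Lyz2 had 3.88 in MEF, 2.17 with GKOSM and 1.41 with KOSM, and Fcer1g -1.65, -2.46 and -2.63 in the same order. Tyrobp had -1.60, -2.96 and -4.04, and Cd14 -0.72, -1.18 and -0.08. The macrophage list shares no gene with the interferon list, although the MEF array itself had all 10 well above background. A different interferon response to the vectors, a response within a few macrophages, unequal amounts of vector and chance differences between cultures were not tested and all stay open.

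Epithelial genes were lower with GKOSM than with KOSM for 11 of 18 (median -1.87), while of 19 pluripotency genes 8 were lower and 11 under 2-fold (median -0.61). Scaling as the whole cause is argued against for the epithelial list by its median, which was at most -1.81 under the 4 scalings, and the pluripotency median was at most -0.55. A mixture of unchanged MEF with KOSM-like cells requires a single share for all genes, but at the lower quartile of the share implied by all 53 cell cycle genes (0.96, and 0.70 under spike-in scaling) 31 of the 37 measured epithelial and pluripotency genes lay below the mixture (33 under spike-in scaling), at a median log2 distance of -1.37 (quartiles -2.21 to -0.31) and of -1.32 (-2.19 to -0.34) under spike-in scaling. The median share implied by the cell cycle genes was 1.12, more than a mixture can give, and 0.81 under spike-in scaling. At 0.96 the mixture is nearly the KOSM array, so the epithelial distance there, -1.86, largely restates GKOSM minus KOSM. The check thus rests on the share taken from cell cycle genes. A mixture in which cells without the vector also proliferate stays open. A difference between the vectors in how they act on these genes was not tested and stays open, as does a difference between cultures.

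The comparison of miPSC with MEF had more genes 2-fold apart than the other comparisons, and miPSC was alone on its slide. After scaling, 8 spike-in probes differed by at most 0.31 between the miPSC and MEF arrays, so the scaling left no 2-fold offset in them. A gain common to all spots of a slide is removed by the scaling from genes and spike-ins alike. These probes therefore cannot show whether the slides differed in gain. Slide effects on single probes cannot be told apart from the group.

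Trophectoderm genes had a median of 1.20 with KOSM and -1.09 with GKOSM relative to MEF, a difference that was not tested. The medians cover different members, 14 with KOSM (6 bounds) and 9 with GKOSM (1 bound, with 7 more dim on both arrays). With genes well above background on both arrays the KOSM value became -0.49, the same sign as with GKOSM. The opposite signs thus depend on members dim in MEF.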

How the results depend on the processing

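Spike-in scaling and the filter on all 4 arrays were chosen after the data were seen, and the other alternatives before. Of the counts, shares and correlations over the alternatives, 130 stayed within their limits and 44 moved. Of the list medians, 1156 kept their side of the random lists, 43 no longer stood apart, 29 newly did and 12 of lists that stood apart changed sign. Of the values of named genes, 3746 kept their side of 2-fold, 76 no longer reached it, 19 newly did and none that was 2-fold apart changed sign. The number of lists that stood apart stayed within 1.5 times in every comparison. Precision is limited by 1 array per group and, for dim genes, by signal over background. The correlations were not run with stricter filters, which keep the genes already used.

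With spike-in scaling, 6425 genes were higher and 2543 lower with KOSM than in MEF, and 721 higher and 3582 lower with GKOSM than with KOSM, which follows from the shift of all genes. With a 4-fold threshold, which lowers counts by construction, higher and lower genes were 1675 and 1492 (KOSM against MEF), 951 and 1067 (GKOSM against MEF), 255 and 653 (GKOSM against KOSM, 28.1% higher) and 2816 and 2486 (miPSC against MEF). With normexp they were 2099 and 2268 for GKOSM against MEF and 705 and 1081 for GKOSM against KOSM. With genes above background on all 4 arrays, which tests fewer genes, 1281 were lower with GKOSM than with KOSM.

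Shares of genes toward miPSC are given for the higher set with KOSM and GKOSM, then the lower set with KOSM and GKOSM. They were 56.9%, 43.0%, 54.6% and 58.5% with spike-in scaling, 52.4%, 42.5%, 61.8% and 55.6% in the unscaled series table, 58.1%, 51.8%, 64.1% and 60% with genes above background on both arrays, 64.1%, 57.8%, 65.6% and 59.8% on all 4 arrays, and 44.5%, 37.9%, 55.4% and 50% for genes 2-fold apart. Single shares moved to 51.5% (higher set, KOSM) with no filter, 43.1% (higher set, GKOSM) with normexp and 65.1% (lower set, GKOSM) with median scaling. The correlation of GKOSM minus KOSM with miPSC minus MEF was -0.174 with normexp and -0.234 with no filter, and that between the vectors 0.835 and 0.736. In the lower set the share with KOSM lay below that with GKOSM under spike-in scaling, against the order under the other settings. Apart from the shift of all genes, the cause was not tested.

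Among lists that stood apart, medians that changed sign were, for GKOSM minus KOSM with spike-in scaling, matrix (-0.22), smooth muscle (-0.1), DNA replication (-0.25) and oxidative phosphorylation (-0.26). This follows from the shift common to genes measured on both arrays. The median over all compared genes, where some bounds do not move, moved by -0.346. The epithelial median of GKOSM minus MEF was -0.01 with no filter. With genes above background on both arrays, and also on all 4, trophectoderm genes had -0.49 for KOSM minus MEF and -0.26 for miPSC minus MEF, and endothelial genes -0.25 for miPSC minus MEF. Mesendoderm genes had -0.42 for miPSC minus MEF on all 4 arrays. The members left out by the filter on both arrays were mostly dim in MEF. With that filter the mesendoderm median did not change sign. The filter on all 4 arrays also left out Foxa2 and Sox17, which were well above background in MEF and miPSC but dim with KOSM.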

Other observations

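The genes below are members of the gene lists and were singled out after their values were seen.

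Hba-a1 and Hbb-y ranked the 2 vectors in opposite order. Hba-a1 had a level of -5.26 in MEF, -0.23 with GKOSM, -3.31 with KOSM and -1.81 in miPSC, so that it was 32.7-fold higher with GKOSM than in MEF and 3.87-fold higher with KOSM. Hbb-y was not well above background in MEF and had -2.32 with GKOSM, -0.89 with KOSM and -6.47 in miPSC, giving bounds of at least 23.1-fold and at least 62.3-fold against MEF. The adult beta-globin gene Hbb-bt had -4.31, -4.51, -5.38 and -4.40 in MEF, GKOSM, KOSM and miPSC.

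Of the cold-inducible RNA-binding protein genes, Cirbp had 1.34 in MEF, 0.71 with GKOSM, -0.46 with KOSM and 3.04 in miPSC, while Rbm3 had 5.52, 5.92, 5.76 and 5.17 in the same order. The label protocols place infection at 32 °C.

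The leukocyte gene Laptm5 went against the macrophage and blood list in miPSC. Its level was -5.05 in MEF, -6.56 with GKOSM, -5.49 with KOSM and 3.96 in miPSC, 516-fold higher than in MEF, whereas Lyz2 was 47.9-fold lower there.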
